A study of Homo sapiens with 15 samples.

How the data were processed

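The series holds small RNA sequencing of 15 libraries of human cells labelled HEK-293, a line derived from embryonic kidney, while the series title speaks of macrophages. Cells were incubated for 18 h with very low-density lipoprotein (VLDL), with VLDL lipid hydrolysis products made by lipoprotein lipase (LPL), or with the hydrolysis products and 20 µM GKT136901, an inhibitor of the NADPH oxidases NOX1 and NOX4. The titles of the VLDL group name pcDNA together with VLDL, without saying what it was. Each of the 3 groups had 5 libraries. Per the labels' protocols, RNA was extracted with TRIzol, treated with DNase, made into libraries with the NEBNext small RNA kit and sequenced on a NovaSeq X. Groups and replicate numbers came from the sample labels.

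The deposited table holds raw read counts per gene, 1 column per library, with no normalization by the authors. Per the submitters' processing notes, fastp 0.24.0 and STAR 2.7.11b were used with the hg38 build, and R 4.4.2, edgeR 4.4.2 and DESeq2 1.46 are named without a role. Per the file headers, the counts were made by featureCounts 2.0.6 over exons grouped by gene, with a RefSeq annotation and without options for strand, multiply mapped reads or overlapping genes. Reads that map to several places were therefore not counted, which leaves out reads shared by identical copies such as let-7 loci, and sense and antisense reads are not told apart. Reads over exons of several genes were not counted either. Of 364 miRNA genes overlapping an exon of another gene, 12.1% had any count, against 46.3% of the 1551 miRNA genes that do not. MIR21, MIR155, MIR146A, MIR142, MIR223, MIR221 and MIR222 lie in such exons and had a count of 0 in every library, so their levels could not be read from this table. MIR132 overlaps an exon of LOC124903896 in part, which covers 1 of its 2 mature arms, and kept 31314 counts. A count is assigned to a precursor gene and not to a miRNA arm, and a count on an mRNA in such a library is a fragment.

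The table lists 50037 genes, of which 21453 had any count. No per-library column was left without a sample. RNA classes came from the RefSeq biotype and gene names (49658 gene names matched, copy suffixes removed), with 0.00315% of counts in genes without a biotype. Genes were kept by the edgeR filterByExpr function (minimum count 10, minimum total count 15), which left 4099 genes holding 99.664% of the counts. TMM factors were computed and each gene was tested with edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3), two-sided, in 1 model of all 3 groups with 12 residual degrees of freedom. Benjamini-Hochberg adjustment ran over all genes tested, and an adjusted p under 0.05 was called. Values per group are means of TMM-scaled CPM with the SD over 5 libraries. The sums of myeloid, HEK-293 and blood cell genes are instead CPM of the total counts, without TMM factors. Log2 differences are from the model, with standard errors (SE).

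The labels give each replicate number a shared experiment (replicates 1 to 5 are experiments 2 to 6), so the numbers pair the libraries. Deviations from group means correlated at r = 0.066 to 0.38 (median 0.11) in the 15 pairs of libraries with the same number. In other pairs the median was -0.07 and the highest 0.15, between replicates 2 and 3. Replicates 4 and 5 reached 0.13, so the 5 experiments were not equally distinct. In 8 of the 15 libraries the best mean correlation was with their own number. The first principal component held 14.9% of the variance, and experiment accounted for 95.4% of it; the second held 12% and experiment accounted for 96.7% of it. The labels do not say whether the authors used the experiment in their model. The tests were fitted without it, and the fit with the experiment as a block (8 residual degrees of freedom) was an alternative; blocked values are given where they change a call. Biological coefficients of variation were 0.583 without the block and 0.513 with it. The labels do not say whether the cells of an experiment came from a separate passage, and the p-values measure the spread between these libraries, which may be partly technical. Pairs of libraries within a group differed far beyond sampling noise (chi-square per degree of freedom 12.1 to 308), so none was counted as a repeat of another.

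Of 15 gene lists, the 14 with at least 3 tested members were compared with all other genes by limma's camera (limma 3.58.1) with a preset correlation of 0.01, adjusted over the 14 lists of a comparison. The lists cover miRNAs tied to lipid metabolism, to NOX and redox control and to inflammation, the let-7 family, the miR-17-92 clusters, snoRNAs of oxidative and lipid stress, GAS5-hosted snoRNAs, Y and vault RNAs, mitochondrial tRNAs, and mRNAs of the PPAR, SREBP, NRF2, stress and NADPH oxidase programs; miRNAs of blood, liver, muscle and endothelium had 2 tested members and no list test. Shares of each RNA class were compared by an exact two-sided permutation test of 5 against 5 libraries, over 252 assignments, adjusted over 51 tests. Genes to be named were set by a rule: up to 10 genes per direction with the lowest p among those called; where fewer than 10 were called, the 10 genes with the lowest p, as values only; up to 4 members per list with the lowest p; and the 5 genes with the highest mean CPM. Not all genes that this rule sets are given in the text. Groups, tests, lists, naming rule and the alternatives below were fixed before the data were examined. The alternatives were DESeq2 size factors, library-size scaling, other filters, DESeq2 1.42.0, limma voom with quality weights, the block, the compared groups alone, miRNA genes alone, an adjusted p under 0.1, an estimated correlation in camera, and each library left out in turn.

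The tests were run on simulated data with known changes. For LPL against VLDL, over 3496 simulated genes, the model without the block called 0% of genes changed 1.5-fold, 4.48% of genes changed 2-fold and 25.8% of genes changed 4-fold, and 92.3% of 4-fold changes in genes above a mean of 10 CPM; the blocked model called 13.4%, 19.4% and 51.5%, and 100% of those 4-fold changes. Over all changed genes, for GKT136901 against LPL:VLDL alone the blocked model called 2.99%, 13.4% and 42.4%, and against VLDL 1.49%, 16.4% and 48.5%; without the block these were 0%, 2.99% and 25.8%, and 0%, 4.48% and 24.2%. Above a mean of 10 CPM the blocked model called 33.3% and 20% of 1.5-fold changes in these comparisons (6 and 5 genes). It called 87.5% and 90.9% of 2-fold changes there (8 and 11 genes). The blocked model also called 1 unchanged gene in each of the 2 comparisons with VLDL and 0 in the other, and the model without the block 0 in all 3. Total counts ran from 5076917 to 9757123 per library. Most counts fell on snoRNAs and miRNAs, and mRNA fragments were seen at a few CPM.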

Results

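Small RNA was sequenced from 15 libraries labelled HEK-293 cells, 5 given VLDL (titled pcDNA:VLDL), 5 given the lipid products that LPL releases from VLDL (LPL:VLDL), and 5 given these products with 20 µM GKT136901. Total counts ran from 5076917 (5.08 M) to 9757123 (9.76 M) per library, with a mean of 8.85 M ± 1.14 (SD, n = 15). The means were 9.18 M ± 0.603 with VLDL, 9.22 M ± 0.382 with LPL:VLDL and 8.16 M ± 1.78 with GKT136901 (SD, n = 5 each), where replicate 2 held 5.08 M. Between 8840 and 10862 genes had a count in a library.

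C/D box snoRNAs, the guides of ribosomal RNA methylation, held 56.7% of all counts, and miRNAs held 38.9%. Y RNAs held 1.27%, mRNA fragments 1.1%, nuclear tRNAs 0.778%, mitochondrial tRNAs 0.149% and mitochondrial rRNAs 0.095%. The 5 most abundant genes were MIR148A (mean 114000 CPM), MIRLET7I (108000 CPM), SNORD49A (84500 CPM), SNORD50A (70100 CPM) and SNORD44 (48100 CPM). Shares of miRNA were 37.8% ± 5.22 with VLDL, 38.8% ± 7.04 with LPL:VLDL and 39.9% ± 6.76 with GKT136901 (SD, n = 5 each). None of the 51 comparisons of class shares passed adjustment, and the lowest unadjusted value was an exact permutation p of 0.0397 (two-sided, adjusted p = 1) for snRNA with LPL:VLDL against VLDL. The smallest p this design allows is 0.00794, which a single class could not bring past adjustment over 51 tests. Y RNA was at 3.12% to 3.25% in the 3 libraries of experiment 2 and at 0.546% to 1.05% in the other 12 libraries, at means of 1.31% ± 1.01 (VLDL), 1.25% ± 1.13 (LPL:VLDL) and 1.29% ± 1.11 (GKT136901) (SD, n = 5 each).

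**Figure D1:**
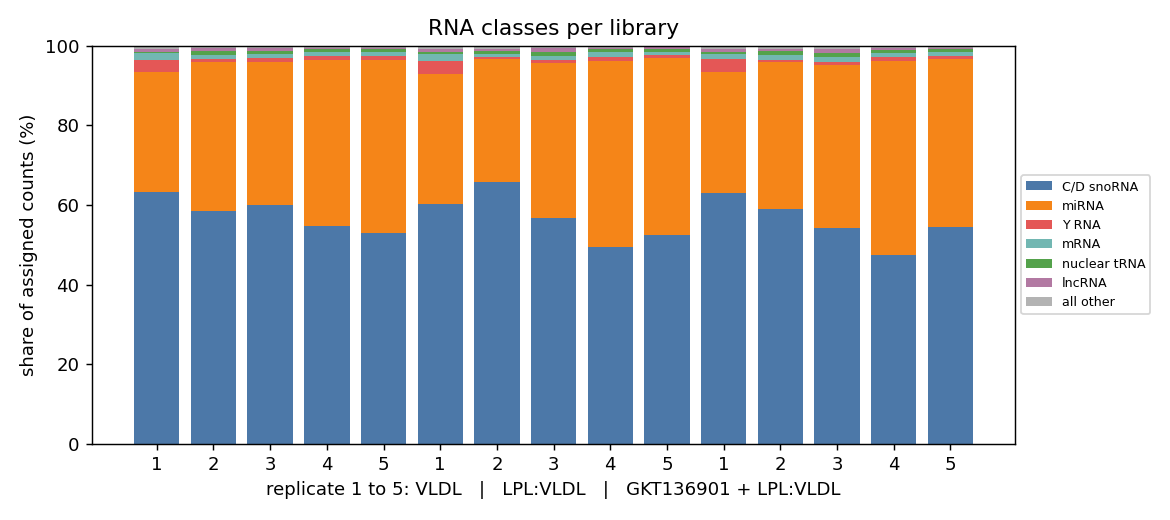
Share of assigned counts per RNA class (percent, stacked bars) in each of the 15 libraries, by group and replicate. C/D snoRNAs and miRNAs held 56.7% and 38.9% of all counts, and the Y RNA share was highest in replicate 1 of each group (3.12%, 3.25% and 3.24%).

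The mRNA fragments included those of genes known from macrophages and other myeloid cells. CSF1R, the receptor of macrophage colony-stimulating factor, had 1771 counts over the 15 libraries, ITGB2, the integrin chain of leukocytes, had 1382, SPP1 had 1316 and LAPTM5 had 935. These 4 held 5404 of the 6919 counts of 18 myeloid genes, whereas CD68 had 56, CD14 31, LYZ 30 and AIF1 0. The summed level of 18 myeloid genes was 59.3 CPM ± 26.5 with VLDL, 53.6 CPM ± 41 with LPL:VLDL and 44.4 CPM ± 21 with GKT136901 (SD, n = 5 each), with exact permutation p from 0.389 to 0.714 for the 3 comparisons (two-sided), a test that leaves out the experiment. Within experiments the sum was lower with GKT136901 than with VLDL in 5 of 5 (exact sign-flip permutation p = 0.0625, the smallest that 5 pairs allow). Experiment 2 had the highest sums, at 105, 126 and 81.7 CPM against 28.4 to 60.1 CPM in the other 12 libraries, and without its library the LPL:VLDL mean was 35.5 CPM. The summed level of 18 genes known from HEK-293 cells was 1.4 CPM ± 0.708, 1.03 CPM ± 0.477 and 1.58 CPM ± 0.487 in the same order, with exact permutation p from 0.0952 to 0.651. The sums are CPM of the total counts, without TMM factors. Factors of 1.32 (VLDL), 1.34 (LPL:VLDL) and 1.16 (GKT136901) would lower the sums of experiment 2. These lists were chosen after values of some myeloid genes had been seen, and the sign-flip test after these sums.

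The comparison of LPL:VLDL with VLDL asked how the lipid products of LPL affect small RNA. MIR132 was the gene that stood out: it had 293 CPM ± 75.5 with LPL:VLDL and 189 CPM ± 83.1 with VLDL (SD, n = 5), was higher in 5 of 5 experiments, and differed by 0.63 on the log2 scale (SE 0.27). With the experiment as a block the log2 difference was 0.70 (SE 0.13, a fold of 1.62), and MIR132 rose (edgeR adjusted p = 0.0494), whereas without the block it was not called (adjusted p = 0.999). MIR212, the neighbouring miRNA, which is transcribed with it, had 225 CPM ± 60.6 against 161 CPM ± 89.9 (SD, n = 5), a blocked log2 difference of 0.61 (SE 0.14) and was higher in 4 of 5 experiments (edgeR blocked adjusted p = 0.308). Both lie on the minus strand of chromosome 17 in hg38, MIR132 at 2049908 to 2050008 and MIR212 at 2050271 to 2050380. An exon of LOC124903896 covers 42 of the 101 bases of MIR132. It holds 21 of the 22 bases of the mature arm at 2049929 to 2049950. Reads over both genes were not counted, so the MIR132 counts leave out reads of that arm. Because MIR132 lies on the minus strand, that arm is the downstream one. The MIR132 values, also in the inflammatory list, therefore do not measure the mature miRNA of that arm. The other arm, at 2049965 to 2049986, and MIR212 have 0 bases in such an exon.

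**Figure D2:**
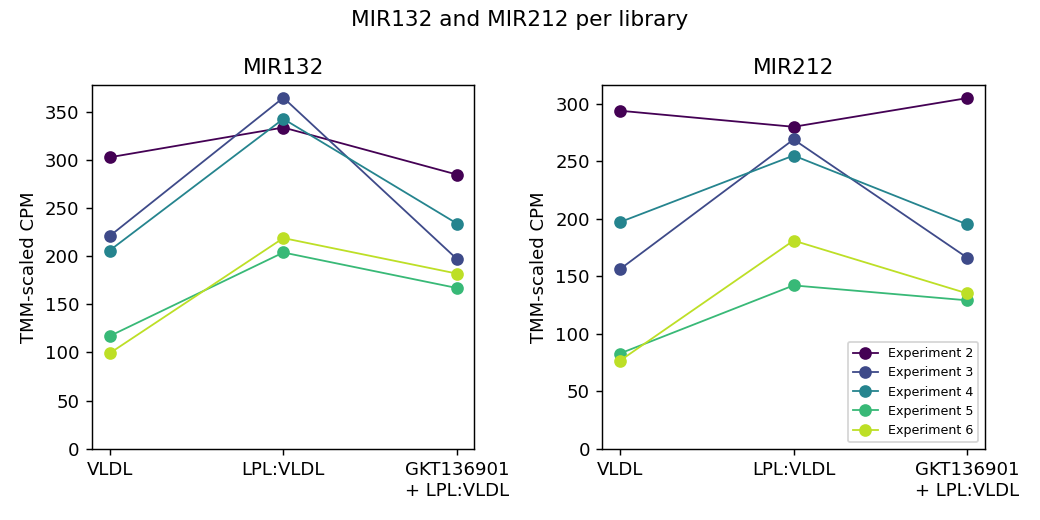
TMM-scaled CPM (vertical axis, from 0) of MIR132 (left) and MIR212 (right) in the 3 groups, with 1 line per experiment and 1 point per library. MIR132 was higher with LPL:VLDL than with VLDL in 5 of 5 experiments, at means of 293 and 189 CPM, and had a mean of 213 CPM with GKT136901.

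Among inflammatory miRNAs, 8 members were tested and 7 had a higher level with LPL:VLDL, at a median log2 difference of 0.19 (6 of 8 and 0.18 with the block). The list passed camera only with the block (adjusted p = 0.0052, and adjusted p = 0.53 with the block and an estimated correlation; adjusted p = 0.51 without the block and 0.91 with an estimated correlation). Since camera set the list against all other tested genes, mostly mRNAs, a shift shared by all miRNAs is not told apart. In the blocked fit 1 member was called over all genes and 2 members, MIR132 and MIR212, adjusted over the list alone; without the block 0 were called either way. MIR146B, a miRNA of the NF-kB response, had 18900 CPM ± 1350 against 16600 CPM ± 1140 (SD, n = 5) and was higher in 5 of 5 experiments, with a log2 difference of 0.19 (SE 0.15).

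Of 18 tested lipid and cholesterol miRNAs, 13 were above 0, with a median log2 difference of 0.063 (camera adjusted p = 0.51). MIR378A, which lies in the gene of the coactivator PPARGC1B, had 40.2 CPM ± 10.4 against 26.2 CPM ± 7.65 (SD, n = 5), higher in 5 of 5 experiments; in the blocked fit it was the 1 member called adjusted over the list alone, and 0 were called over all genes. MIR30C2 had 29.6 CPM ± 5.78 against 24.3 CPM ± 5.35. Of 11 NOX and redox miRNAs, 8 were above 0 (adjusted p = 0.81); MIR25, which targets NOX4, had 7360 CPM ± 640 against 6670 CPM ± 450, and MIR93 had 362 CPM ± 71.9 against 409 CPM ± 95.4. The let-7 list had 6 of 8 members above 0 (adjusted p = 0.57), where MIRLET7I had 122000 CPM ± 32100 against 96400 CPM ± 17500 and was the 1 member called adjusted over the list alone with the block. The miR-17-92 list had 3 tested members, MIR106B, MIR93 and MIR25 of a paralogous cluster (adjusted p = 0.82). The other 12 members, among them all of miR-17-92 itself, had no count. Exons of MIR17HG overlap MIR17, MIR18A, MIR19A, MIR20A and MIR19B1, and exons of MIR106AHG overlap MIR106A, MIR18B, MIR20B, MIR19B2 and MIR363. Reads over both genes were not counted, so the levels of these miRNAs could not be read from this table.

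Stress-related snoRNAs of RPL13A and related loci were above 0 in 6 of 7 members (camera adjusted p = 0.51), and SNORD60, an intracellular cholesterol trafficking snoRNA, had 1630 CPM ± 648 against 1420 CPM ± 151 (SD, n = 5). GAS5-hosted snoRNAs had 5 of 10 members above 0 and a median log2 difference of 0.015, on the other side of 0 from the direction of the test (adjusted p = 0.82). Within them SNORD44 had 52100 CPM ± 12300 against 45000 CPM ± 4330, and SNORD79 had 124 CPM ± 56.8 against 161 CPM ± 43.9 and was lower in 5 of 5 experiments. Y and vault RNAs had 3 of 5 members above 0 (adjusted p = 0.82), with RNY5 at 1330 CPM ± 430 against 1310 CPM ± 389. The 14 tested mitochondrial tRNAs had 6 members above 0 and a median of -0.062, of the other sign than camera's direction (adjusted p = 0.82); TRNF had 1180 CPM ± 396 against 895 CPM ± 335, higher in 4 of 5 experiments. It was the 1 member called adjusted over the list alone with the block (adjusted p = 0.028). Without the block 0 members were called (adjusted p = 0.894). The share of all mitochondrial tRNAs was 0.149% ± 0.0621 against 0.133% ± 0.0569 (SD, n = 5). It was higher in 5 of 5 experiments (exact sign-flip permutation p = 0.0625, the smallest that 5 pairs allow). The exact permutation test that leaves out the experiment gave p = 0.659 (adjusted p = 1). Of the 14 tested members 0 were higher in 5 of 5.

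Among mRNA fragments PLIN2, which coats lipid droplets and responds to fatty acids, had 7.35 CPM ± 3.46 against 6.25 CPM ± 2.84 (SD, n = 5), higher in 5 of 5 experiments, and the PPAR list of 4 tested members had an adjusted p of 0.51. SQLE, an enzyme of cholesterol synthesis, had 2.71 CPM ± 0.434 against 4.39 CPM ± 2.63, and 7 of 9 SREBP targets were below 0 (adjusted p = 0.81). SLC7A11, the cystine transporter and an NRF2 target, had 4.66 CPM ± 1.97 against 2.76 CPM ± 1.21; the NRF2 list had 5 tested members (adjusted p = 0.82). ATF3, a stress transcription factor, had 1.56 CPM ± 0.786 against 2.65 CPM ± 1.31 (list adjusted p = 0.82), and CYBA, the p22phox subunit of NADPH oxidases, had 0.908 CPM ± 1.06 against 1.32 CPM ± 0.717, with 3 of 3 oxidase members below 0 (adjusted p = 0.51). The 3 were CYBA, RAC1 and RAC2. NOX1 had a total count of 1 and NOX4 of 0 over all libraries, too few to test. The lowest p without the block were for VAMP2 at 2.52 CPM ± 1.08 against 0.705 CPM ± 0.321, SRSF8 at 0.7 CPM ± 0.265 against 2.23 CPM ± 0.714, HPS6 at 2.73 CPM ± 1.1 against 0.999 CPM ± 0.343 and NF2 at 0.803 CPM ± 0.332 against 2.22 CPM ± 0.807. MIR126, an endothelial miRNA, had 1040 CPM ± 493 against 974 CPM ± 426, and no other gene of its list but MIR133A2 was tested.

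By edgeR without the block 0 of 4099 genes were called, with 77 (1.88%) at an unadjusted p under 0.05; DESeq2 called 0 (126 under 0.05) and limma voom 0 (142). With the block edgeR called 1 gene (172 under 0.05), DESeq2 1 and limma voom 2, MIR132 among them each time. The edgeR share under 0.05 was thus 1.88% without the block and 4.2% with it. For GKT136901 it was 2.12% and 3.68% against LPL:VLDL, and 2.22% and 4.32% against VLDL. Fits without the block leave out the pairing and gave fewer low p, so their 0 calls are limited evidence of no change. Within the blocked edgeR fit the MIR132 call ended when experiment 4, 5 or 6 was left out (adjusted p = 0.995, 0.491 and 0.997). It also ended without LPL:VLDL replicate 2 (0.0546), under the stricter filter (0.193), with DESeq2 size factors (0.061) and with library-size scaling (0.49), while the log2 difference stayed between 0.59 and 0.81 over the 5 experiments left out in turn.

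The comparison of GKT136901 with LPL:VLDL alone asked what NOX1 and NOX4 inhibition changes in cells given the lipid products. Mitochondrial tRNA counts were higher with the inhibitor: 12 of the 14 tested tRNAs were above 0, at a median log2 difference of 0.31 (a fold of 1.24), and the list passed camera (adjusted p = 0.015). With an estimated correlation the adjusted p was 0.95. TRNL2, the tRNA of leucine on the plus strand of the mitochondrial genome at 12266 to 12336, had 16.2 CPM ± 3.81 with the inhibitor and 9.71 CPM ± 3.07 without it (SD, n = 5), higher in 5 of 5 experiments. TRNP, the tRNA of proline at 15956 to 16023 on the minus strand, had 40.1 CPM ± 6.79 against 28.9 CPM ± 6.61, and TRNS2, the tRNA of serine at 12207 to 12265, had 104 CPM ± 42.2 against 78.8 CPM ± 25.6, each higher in 5 of 5 experiments. Of the 14 tested tRNAs 4 were higher in 5 of 5 experiments. Log2 differences of the 14 ran from -0.18 to 1.09. TRNF had 1270 CPM ± 435 against 1180 CPM ± 396 and was higher in 3 of 5.

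Over all genes 0 members of the mitochondrial tRNA list were called and 0 adjusted over the list alone, and in the blocked fit 0 and 2, the 2 being TRNL2 and TRNP. The list's call ended without GKT136901 replicate 1, 2 or 3 (adjusted p = 0.094, 0.28 and 0.17) and without LPL:VLDL replicate 4 or 5 (0.38 and 0.43), and held in each blocked fit with 1 experiment left out (adjusted p from 0.0023 to 0.021). The mitochondrial rRNAs RNR1 and RNR2, added after the list's result was seen, had blocked log2 differences of 0.21 and 0.14, and the 164 tested nuclear tRNAs a median of -0.012. The mitochondrial rRNA share was 0.105% ± 0.0298 against 0.0883% ± 0.0271 and the mitochondrial tRNA share 0.174% ± 0.0621 against 0.149% ± 0.0621 (SD, n = 5). Each was higher in 5 of 5 experiments (exact sign-flip permutation p = 0.0625 each, the smallest that 5 pairs allow). The exact permutation test that leaves out the experiment gave p = 0.405 and 0.532 (adjusted p = 1 each).

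**Figure D3:**
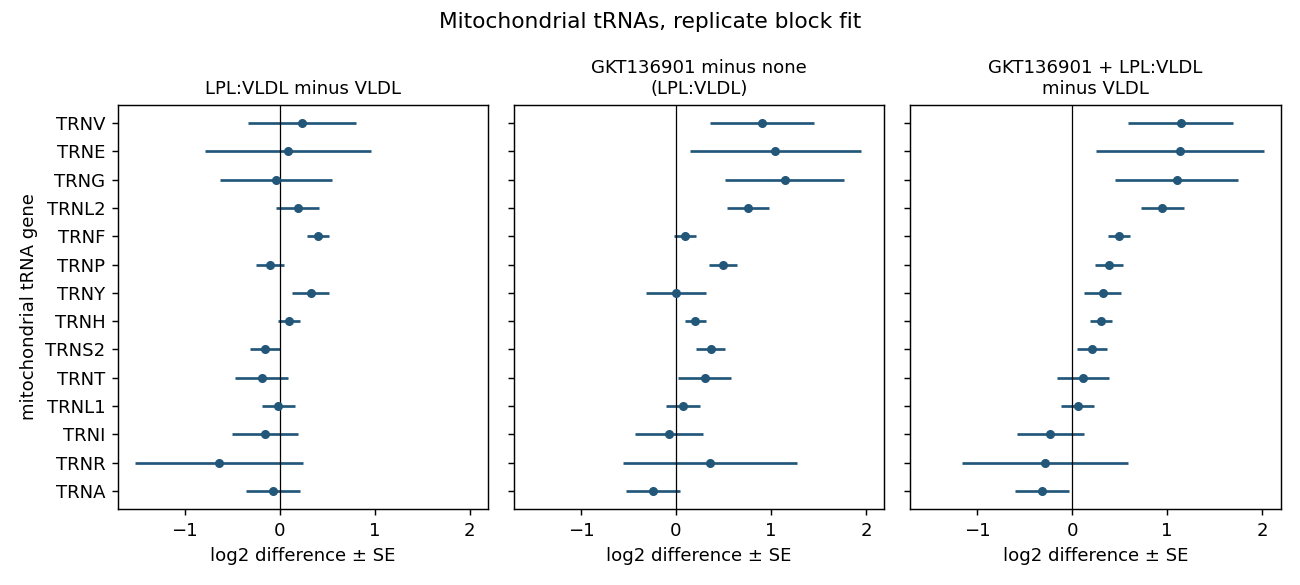
Log2 differences (horizontal axis; points with bars of 1 SE, from the fit with the experiment as a block) of the 14 tested mitochondrial tRNA genes in the 3 comparisons. The list median was 0.33 for GKT136901 against LPL:VLDL alone, 0.31 for GKT136901 against VLDL and -0.029 for LPL:VLDL against VLDL.

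MIR132 had 213 CPM ± 47.5 with GKT136901 against 293 CPM ± 75.5 without it (SD, n = 5), lower in 5 of 5 experiments, with a blocked log2 difference of -0.44 (SE 0.13) that did not pass over all genes (edgeR adjusted p = 1). Both comparisons use the same LPL:VLDL libraries, so a high value there by chance would also give a fall. Adjusted over the list alone it was the 1 inflammatory miRNA called with the block. MIR212 had 186 CPM ± 71.4 against 225 CPM ± 60.6. The inflammatory list had 5 of 8 members below 0 (camera adjusted p = 0.93) and the let-7 list 6 of 8 (adjusted p = 0.93), where MIRLET7I had 106000 CPM ± 22700 against 122000 CPM ± 32100. MIR93 had 446 CPM ± 76.7 against 362 CPM ± 71.9, was higher in 5 of 5 experiments, and was the 1 member of the miR-17-92 list called adjusted over the list alone with the block (list adjusted p = 0.93). Its blocked edgeR adjusted p was 0.0348 over the 3 tested members of that list. Over the NOX and redox list, which also holds MIR93, it was 0.128 and MIR93 was not called. The NOX and redox list had 8 of 11 members above 0 (adjusted p = 0.75) and the lipid and cholesterol list 9 of 18 (adjusted p = 0.93), with MIR185 at 909 CPM ± 163 against 804 CPM ± 143.

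SNORD78, a GAS5-hosted snoRNA, had 852 CPM ± 165 against 667 CPM ± 57.8 (SD, n = 5), higher in 5 of 5 experiments, in a list with 3 of 10 members above 0 (camera adjusted p = 0.93). The stress snoRNAs had 2 of 7 members above 0 and the Y and vault RNAs 3 of 5 (adjusted p = 0.93 each). PLIN2 had 4.34 CPM ± 2.14 against 7.35 CPM ± 3.46. GCLC, an enzyme of glutathione synthesis, had 1.83 CPM ± 0.604 against 3.49 CPM ± 0.826, and GCLC was lower in 5 of 5 experiments. Their PPAR and NRF2 lists had adjusted p of 0.93 each, as had the SREBP and stress lists, and the NADPH oxidase list had 0.75. CDKN1A, the p53 target that encodes a cell cycle inhibitor and was chosen after its values were seen, had 11.8 CPM ± 3.31 against 6.81 CPM ± 2.35, higher in 5 of 5 experiments. The lowest p without the block belonged to genes near the limit of detection: PCGF1 at 0.112 CPM ± 0.16 against 1.56 CPM ± 0.479 and ITGAM at 0.0414 CPM ± 0.0925 against 0.966 CPM ± 0.953, while SLC12A4 had 1.22 CPM ± 0.644 against 0.0868 CPM ± 0.194.

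By edgeR 0 genes were called without the block (87, or 2.12%, at an unadjusted p under 0.05) and 0 with it (151). DESeq2 called 0 and 0 (128 and 232 under 0.05), and limma voom 0 and 0 (115 and 230).

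The comparison of GKT136901 and LPL:VLDL with VLDL asked what differs from the control when the inhibitor is present. Both GKT136901 comparisons use the same 5 inhibitor libraries, so agreement between them is no separate evidence. Mitochondrial tRNAs had 11 of 14 above 0, a median log2 difference of 0.31 (a fold of 1.24) and a camera adjusted p of 0.0081. With an estimated correlation the adjusted p was 0.93, and 0.026 with the block as well. TRNL2 had 16.2 CPM ± 3.81 against 8.33 CPM ± 2.14 (SD, n = 5), TRNF, the tRNA of phenylalanine, 1270 CPM ± 435 against 895 CPM ± 335, and TRNV, the tRNA of valine, 2.34 CPM ± 0.437 against 1.1 CPM ± 0.571, each higher in 5 of 5 experiments. Of the 14 tested tRNAs 6 were higher in 5 of 5 experiments. Log2 differences of the 14 ran from -0.32 to 1.32. LPL:VLDL alone already had TRNF at 1180 CPM ± 396, so most of its mean difference from VLDL was present without the inhibitor.

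Of the 14 mitochondrial tRNAs 0 were called over all genes and 1, TRNL2, adjusted over the list alone; with the block these were 0 and 4, the 4 being TRNL2, TRNF, TRNP and TRNH (the last named after its values were seen). The list's call ended without GKT136901 replicate 1, 2 or 3 (adjusted p = 0.073, 0.19 and 0.089) and without VLDL replicate 5 (0.35), and held in each blocked fit with 1 experiment left out (7e-05 to 0.0027).

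Lists of miRNAs were mostly above 0 here. Of the lipid and cholesterol miRNAs 16 of 18 members were above 0 (camera adjusted p = 0.29), of the NOX and redox miRNAs 10 of 11 (0.19) and of the inflammatory miRNAs 8 of 8 (0.29). With the block these lists passed (adjusted p = 0.023, 0.023 and 0.036), and with the block and an estimated correlation they did not (adjusted p = 0.45 each). Here too camera set each list against all other tested genes, mostly mRNAs. A shift shared by all miRNAs is therefore not told apart from one of these lists. MIR378A had 34.5 CPM ± 5.35 against 26.2 CPM ± 7.65 (SD, n = 5), MIR185 909 CPM ± 163 against 765 CPM ± 177, MIR23B 93.6 CPM ± 26.1 against 78.6 CPM ± 16.9, MIR28 2520 CPM ± 322 against 2250 CPM ± 421 and MIR146B 18500 CPM ± 952 against 16600 CPM ± 1140. In these lists 0 members were called over all genes and 0 adjusted over the list alone, with and without the block. MIR132 had 213 CPM ± 47.5 against 189 CPM ± 83.1 and was higher in 3 of 5 experiments. The let-7 list had 7 of 8 members above 0. The miR-17-92 list, tested only by MIR106B, MIR93 and MIR25, had 3 of 3 (adjusted p = 0.81 each).

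Among mRNA fragments INSIG1, a regulator of sterol synthesis, had 2.71 CPM ± 1.23 against 4.36 CPM ± 1.66 (SD, n = 5), lower in 5 of 5 experiments, GCLC 1.83 CPM ± 0.604 against 3.53 CPM ± 1.52 and SLC7A11 4.76 CPM ± 2.31 against 2.76 CPM ± 1.21. The SREBP and stress lists had adjusted p of 0.81 each, the NRF2 list 0.98, and the PPAR and NADPH oxidase lists 0.96 each. The stress snoRNAs had 0.81, the GAS5-hosted snoRNAs 0.98 and the Y and vault RNAs 0.96. The lowest p belonged to KRR1, a ribosome assembly factor, at 0.0631 CPM ± 0.0931 against 1.46 CPM ± 0.504, HECA at 1.53 CPM ± 0.792 against 4.19 CPM ± 1.3 and GFI1, a transcriptional repressor of blood cells, at 0.624 CPM ± 0.332 against 2.41 CPM ± 1.4. Each of these 3 was lower in 5 of 5 experiments.

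By edgeR 0 genes were called without the block (91, or 2.22%, at an unadjusted p under 0.05) and 0 with it (177, lowest adjusted p = 0.0579). DESeq2 called 0 and 2 (128 and 249 under 0.05), and limma voom 0 and 4 (171 and 262). The 2 were LOC105371225 and MIR139, and the 4 were LOC105371225, TRNF, TRNL2 and KRR1. LOC105371225, a gene whose exons overlap 1 tRNA gene, had 2190 CPM ± 469 against 1570 CPM ± 463, and MIR139 had 84.3 CPM ± 68.2 against 57.1 CPM ± 47 (SD, n = 5), each higher in 5 of 5 experiments; both were chosen after their values were seen.

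Across 4099 genes, which are not independent replicates, the log2 differences of LPL:VLDL against VLDL and of GKT136901 against LPL:VLDL alone correlated at r = -0.49 (covariance -0.13). Both use the same LPL:VLDL libraries, and unchanged groups simulated on them gave r = -0.5 (range -0.53 to -0.46) and a covariance of -0.13, over 50 simulations. With the shared libraries split between the comparisons in 10 ways the median r was 0.057 (0.0035 to 0.11). For the 471 genes with a mean above 10 CPM it was 0.37 (0.029 to 0.62) and for miRNA genes -0.0063 (-0.088 to 0.21). In each split the comparisons hold LPL:VLDL libraries of different experiments, set against all 5 libraries of VLDL or GKT136901. Experiment differences then push r up, so the split r cannot show whether genes moved back with the inhibitor. How much of the higher value comes from this was not tested. For miRNA genes r was -0.57, within the simulated range of -0.63 to -0.38.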

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

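The screen of the summed myeloid and HEK-293 levels was chosen after their values were seen, and some of the genes screened were named for a low p. Of 198 sets of 5 libraries screened, 17 had a library far from the other 4, and 14 of the 17 were replicate 1 (experiment 2). A rate of 5% would give 9.9, but the sets share the same libraries, so 17 is no measure of an excess. In 2 of the 17 the other 4 libraries had 0, where any count is flagged, so these 2 carry no information, which leaves 15, with 12 in replicate 1.

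Y RNA held 3.12% of the counts in VLDL replicate 1, 3.25% in LPL:VLDL replicate 1 and 3.24% in GKT136901 replicate 1, against at most 1.05% in any other library. RNY5 followed, at 2080 CPM in LPL:VLDL replicate 1 and 2580 CPM in GKT136901 replicate 1, where the nearest others had 1270 and 1350 CPM. In the same experiment MIR378A was low, at 12.6 CPM with VLDL and 21.8 CPM with LPL:VLDL (nearest others 28.6 and 42.7 CPM), and SNORD60 was low with VLDL at 1150 CPM (nearest other 1440 CPM). VLDL replicate 1 also had an mRNA share of 1.57% (nearest other 1.07%). The summed level of 18 myeloid genes was 105 CPM in VLDL replicate 1, 126 CPM in LPL:VLDL replicate 1 and 81.7 CPM in GKT136901 replicate 1 (nearest others 60.1, 46.8 and 37.1 CPM). All 3 groups of experiment 2 shared the high Y RNA share and the high myeloid sum.

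GKT136901 replicate 1 had ITGAM at 0.207 CPM and LPL:VLDL replicate 1 had SLC12A4 at 0.434 CPM, where the other 4 libraries of each group had 0, so that any count would have been flagged. LPL:VLDL replicate 2 had TRNV at 2.63 CPM (nearest other 1.04 CPM), and VLDL replicate 4 had HECA at 6.42 CPM (nearest other 3.97 CPM). GKT136901 replicate 2 held 5076917 counts (5.08 M), where the nearest other library of its group held 8.36 M.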

How the results depend on the processing

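Tests chosen after the result was seen were the blocked fits with limma voom, with miRNA genes alone, with DESeq2 size factors, with library-size scaling, with the stricter filter, with an estimated correlation, without single experiments or without LPL:VLDL or GKT136901 library 2, and the fit without experiment 2. Without the replicate block, counts of called genes stayed at 0 in all 3 comparisons under each planned scaling, filter, tool, threshold and left-out library, and without experiment 2. With the replicate block, LPL:VLDL against VLDL called 1 gene in edgeR and 1 in DESeq2, 2 in limma voom, 3 among miRNA genes alone (MIR374A, MIR132 and MIR378A), 1 without LPL:VLDL library 2 (SNORA18, with MIR132 lost), 1 without GKT136901 library 2, 1 without experiment 2 and 2 without experiment 3; it called 0, MIR132 lost, with DESeq2 size factors, with library-size scaling, with the stricter filter and without experiment 4, 5 or 6. GKT136901 against VLDL called 2 genes in DESeq2 with the block, 4 in limma voom with the block and 1 in the block without LPL:VLDL library 2 (LOC105371225). GKT136901 against LPL:VLDL called 0 in each of these. The cause of these differences was not tested.

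Camera called 2 list tests of 42 without the block, 6 with it, 6 with the block and DESeq2 size factors, 8 with the block without experiment 3, 4 with the block without experiment 6, 0 with an estimated correlation and 1 with the block and an estimated correlation. Leaving out a library gave 0 to 4. The mitochondrial tRNA list had adjusted p = 0.95 (GKT136901 against LPL:VLDL) and 0.93 (against VLDL) with an estimated correlation, 0.05 for the former with the block as well, and ranges of 0.0024 to 0.43 and 0.00091 to 0.35 with 1 library left out; its median stayed above 0. Let-7 and NADPH oxidase lists reached adjusted p = 0.03 each for LPL:VLDL against VLDL with 1 library left out. In 16 list values and 8 gene values the direction differed from that reported with neither value called. Class shares had 0 calls in each setting, where the smallest permutation p possible were 0.00794 (0.0625 within pairs) over 51 tests, so these 0 calls say little. Adjusted over a list alone, the block raised the called members of the mitochondrial tRNAs from 0 to 1 (TRNF) for LPL:VLDL against VLDL, 0 to 2 and 1 to 4 in the GKT136901 comparisons, and of other lists as reported. The block changed no other call.

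The relation of the contrasts went from r = -0.49 to 0.057 (median), 0.0035 (lowest) and 0.11 (highest) when the LPL:VLDL libraries were split, and was -0.57 for miRNA genes and -0.5 with the block. Experiment differences push the split values up, so this rise does not show whether genes moved back. Library-size scaling put the median log2 difference of all genes at -0.11 for LPL:VLDL against VLDL (-0.14 with the block), against 0.0097 with TMM; the mitochondrial tRNA median with GKT136901 was 0.27 to 0.42 over all scalings. Depth limits mRNA fragments and rare tRNAs at a few CPM, where a fold change rests on few counts.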

Other observations

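Tests chosen after the result was seen were those of HEK-293 cells alone, with and without the 4 most counted myeloid genes, of scaling for the mitochondrial tRNAs, and of scaling and of single experiments for MIR132; the lists of myeloid and HEK-293 genes were also written then. The list of blood cell genes and the other tests below preceded their results.

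A few further genes, chosen after their values were seen, differed with LPL:VLDL without passing a test over all genes. MIR320A had a log2 difference of 0.37 (SE 0.17) against VLDL, higher in 5 of 5 experiments, and MIR374A one of -0.25 (SE 0.28), lower in 5 of 5, neither called over all genes (edgeR adjusted p = 0.999 each), and MIR374A was called with the block among miRNA genes alone.

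Transcripts of myeloid genes were found in libraries labelled HEK-293. The sum of 18 myeloid genes exceeded that of 18 HEK-293 genes in 15 of 15 libraries (medians 41.9 and 1.44 CPM), which goes against HEK-293 cells alone. CSF1R, ITGB2, SPP1 and LAPTM5 gave 78.1% of the myeloid counts, and the sum of the other 14 still exceeded the HEK-293 sum in 15 of 15. HOXA9, which some myeloid cells also express, gave 127 of the 178 HEK-293 counts. RNA of red cells, neutrophils and platelets carried with the lipoprotein is argued against by 8 genes of these cells. Their sum over the myeloid sum had a median of 0 (highest 0.003). Other blood cells were not tested by these genes. Some myeloid genes also had few or no counts (CD14 31, LYZ 30, AIF1 0), so low counts of a few genes are limited evidence. The label may name another culture than the one sequenced, which was not tested, and the title's macrophages stay a hypothesis.

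Mitochondrial tRNAs were higher with GKT136901. Scaling is argued against by list medians of at least 0.31 against LPL:VLDL under library-size and DESeq2 scaling, with and without the block. More mitochondrial RNA of every kind may still contribute, since the interval of RNR1 reached 0.44 against a list median of 0.33. The mitochondrial rRNA share was also higher in 5 of 5 experiments against LPL:VLDL. A rise of all tRNA fragments was to be excluded only by a gap between the medians above the interquartile range of nuclear tRNAs. The 164 tested nuclear tRNAs had a median of -0.012 and an interquartile range of 0.37, so this rule did not exclude it. That range is the spread between genes and not the error of their median, and the median itself shows no rise of nuclear tRNAs as a set. The nuclear tRNA share was higher in 4 of 5 experiments against LPL:VLDL, so the question stays open. Chance could not be excluded against LPL:VLDL, where 9 of 100 splits of the libraries gave a camera p as small (real 0.00108, smallest other 3.32e-06), and against VLDL 3 of 100 did (real 0.000578, smallest other 4.97e-05), which argues against chance in that count alone, since the call ended with an estimated correlation (adjusted p = 0.93) or with some single libraries left out. The other splits with a p as small parted 1 or 3 of the 5 pairs of an experiment, where the real ones part 5, and none of the drawn splits that part 5 gave one. Among the 16 swaps within experiments, too few for a share under 0.05, the blocked p were 6.85e-05 and 8.73e-06 against smallest others of 0.00421 and 0.000357; an effect of the inhibitor on mitochondrial tRNA stays a hypothesis.

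With LPL:VLDL, MIR132 was higher in 5 of 5 experiments and MIR212 in 4 of 5. MIR132 was called with the block (adjusted p = 0.0494) and not without it (0.999), and its call was lost without experiment 4, 5 or 6; MIR212 was not called over all genes (blocked adjusted p = 0.308). For MIR132 the difference rests on reads outside the arm that an exon of LOC124903896 covers. A single experiment as the source is argued against by a blocked log2 difference of MIR132 of at least 0.59 with any 1 experiment left out, and scaling by one of at least 0.545 under 3 other scalings. The call ended under library-size scaling, where the difference went from 0.70 (SE 0.13) to 0.545 (SE 0.125, adjusted p = 0.49), a smaller value at a similar error, and under DESeq2 size factors, at 0.69 (SE 0.133, adjusted p = 0.061), just above the threshold. Chance was tested in 16 swaps within experiments, too few for a share under 0.05: the real grouping called 1 gene and the highest other 0. A response to lipid products stays a hypothesis.

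Counts of called genes were 0 in each comparison without the block, so all 100 of 100 splits gave as many, and the highest other split called 3, 4 and 7 genes for LPL:VLDL against VLDL, GKT136901 against LPL:VLDL alone and GKT136901 against VLDL.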
